A study of Homo sapiens with 2 samples.

How the data were processed

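RNA sequencing was done on MCF7 cells, an estrogen receptor positive human breast cancer cell line, in a derivative resistant to palbociclib at 100 nM. Palbociclib inhibits the cell-cycle kinases CDK4 and CDK6. The resistant cells without further treatment (Control) were compared with the same cells given JQ1, an inhibitor of the bromodomains of BET proteins, at 300 nM for 24 hours. Per the labels' protocols and the series' design text, total RNA was depleted of ribosomal RNA, made into libraries with a Kapa RNA HyperPrep kit and sequenced as paired ends on an Illumina NovaSeq. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a and the genome build was hg38. The authors deposited 1 table of raw whole-number counts per gene, with gene symbols and no normalization. The gene annotation and the strand setting of the counting are not given in the sources used here.

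GEO holds 1 sample record per condition, and the count table holds 3 numbered columns per condition. The columns were used as libraries, because pairs within a condition differed by far more than sampling noise: the chi-square per degree of freedom over genes with at least 50 counts lay between 10.5 and 73.0, where Poisson noise gives 1. Nothing says that the libraries came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. No sample or column was left out of the main comparison. The table lists 28008 genes, of which 6688 had no count in any library, and each symbol stands once. Of the symbols, 26576 matched the RefSeq annotation of GRCh38 (the hg38 assembly), directly or through an older symbol, and 25348 had a transcript length. Coordinates, counted from 1, and biotypes come from that annotation.

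Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by the trimmed mean of M-values (TMM), and JQ1 was compared with Control by the quasi-likelihood F-test with robust dispersion. P-values were adjusted by the Benjamini-Hochberg method, and a gene rose or fell where its adjusted p was 0.05 or less. Levels are CPM (counts relative to the library total) scaled by TMM, as mean ± SD of 3 libraries per group. Fold changes are on the log2 scale, JQ1 over Control, with their standard error. For a gene with no count in a group, the fold is a bound computed from 3 counts over that group, which covers counting error only.

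Gene lists were fixed from textbook knowledge before the data were examined, as were 32 single genes, the tests and most alternatives. The lists were BET proteins and P-TEFb regulators, replication-dependent histones, estrogen-induced genes, luminal identity genes, DNA replication and E2F targets, mitosis and G2/M genes, G1/S regulators, MYC and ribosome biogenesis, interferon-stimulated genes, NF-kB and inflammatory genes, AP-1 and MAPK-output genes, growth factor receptors and adaptors, apoptosis regulators, p53 targets, cholesterol synthesis, lysosome and autophagy, epithelial-mesenchymal and TGF-beta genes, unfolded protein response, NRF2 and iron or redox genes, neuronal genes, ribosomal proteins, basal and myoepithelial markers, fibroblast and endothelial markers, and leukocyte markers. Mitochondrially encoded genes matched no symbol and were not analysed here. The 23 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists.

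The named genes are, first, the 12 highest and the 12 lowest by log2 fold change among genes that passed the test, had a mean of at least 5 CPM over the group means, showed no overlap between the libraries of the groups, and carried no LOC, LINC, MIR, SNOR, RN7, ENSG or antisense name. The 32 fixed genes are named whatever their result, and each list adds up to 4 members with the largest absolute log2 fold change among those that passed. Where a count of 5 or fewer list members is opened by name, those names were chosen after their values were seen.

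Each alternative replaced 1 step, except that DESeq2 came with its own size factors and that the GC and length offsets kept only the 14383 genes with an annotated transcript. Scaling was replaced by DESeq2's size factors, upper-quartile factors or library size alone, and the filter by none or by at least 5 CPM. The test was replaced by DESeq2 1.42.0, by limma-voom or by edgeR's glmTreat against a 1.2-fold change. Other fits took the library number as a block, left ribosomal protein and histone genes out before scaling, or left out each library in turn. The set test was repeated with an estimated correlation and with fry. Chosen after the data were seen were thinning all libraries to the smallest total, offsets for transcript GC content and length (loess span 0.3), and leaving out both libraries numbered 3. Gene families sharing the letters of their symbol were compared with all other tested genes by a two-sided Fisher's exact test.

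The tests were run on simulated counts drawn from the real means and library sizes of this comparison, with 15081 genes fitted. edgeR recovered 65.7% of 67 genes changed by 1.5-fold, 86.4% of 66 changed by 2-fold and 100% of 65 changed by 4-fold. Of its 189 calls, 6.88% were unchanged genes. These genes went up and down in like numbers, and beyond them only a list of 40 genes, raised 1.3-fold, was changed. In the real comparison 59.4% of the tested genes changed, so these shares need not hold there. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

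Several features of the processing bear on the measurements. Ribosomal RNA depletion keeps transcripts without a poly(A) tail, such as most histone mRNAs. Reads of near-identical genes (histone, U1 and ribosomal protein genes, and their pseudogenes) can be split or dropped by the counting, so single values of these genes are uncertain. With the strand setting not given, reads of overlapping antisense genes cannot be told apart. No spike-in RNA is described, so all levels are relative to the other RNA of the same library.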

Results

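Gene expression was measured by RNA sequencing in palbociclib-resistant MCF7 breast cancer cells without (Control) or with the BET bromodomain inhibitor JQ1, in 3 libraries per group. The gene counts summed to 67618745, 59579636 and 72109116 in the Control libraries and to 56151676, 50342325 and 46960385 in the JQ1 libraries. The 10 most abundant genes took 5.53% to 5.78% of the counts in Control and 7.92% to 8.18% in JQ1. On log2 CPM the first principal component held 85.1% of the variance and separated the groups. The second held 7.07%. In each group the library numbered 3 stood apart from the others in GC content. For this, the log2 CPM of each gene was taken relative to its mean over all libraries of both groups. The GC contrast is the median of the most GC-rich decile of transcripts minus that of the most GC-poor decile. Each library's value thus also depends on the other group. The GC contrast was 0.56 (log2) in Control library 3, against 0.17 and -0.0041 in the other Control libraries. It was -0.69 in JQ1 library 3, against 0.08 and -0.10 in the other JQ1 libraries.

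The comparison of JQ1 with Control asks which transcripts change when BET proteins are inhibited in cells that have become resistant to a CDK4/6 inhibitor. Of the tested genes 59 of 60 for DNA replication, 57 of 60 for mitosis and 21 of 31 for G1/S control fell. So did 37 of 45 for MYC and ribosome biogenesis and 26 of 37 for the estrogen response. The lists share members, so their counts are not independent. The G1/S list shares CCNE1, CCNE2, E2F1 and E2F2 with DNA replication, and CCNA2 and FOXM1 with mitosis. It shares MYC and CDK4 with the MYC list, and CCND1 with the estrogen list. These lists were lower than other genes by camera with its preset correlation, but with an estimated correlation their adjusted p was 0.0715, or 0.0767 for mitosis. Among the genes that fell were E2F2 (log2 fold change -5.71 ± 0.30 SE), GREB1 (-3.36 ± 0.10), CCND1 (-1.39 ± 0.10) and MYC (-1.25 ± 0.096). Higher were the BET inhibitor response genes HEXIM1 (1.496 ± 0.102) and SERPINI1 (3.70 ± 0.14), as well as BRD2 (1.47 ± 0.099) and 25 of 43 lysosome and autophagy genes, a list with an adjusted p of 0.476 with an estimated correlation. Of 15239 genes tested, 9053 changed (59.4%), 4268 of them up and 4785 down. More than 2-fold changes were seen in 3158 genes, of which 941 rose and 2217 fell (973 and 2120 with both libraries numbered 3 left out), and more than 4-fold changes in 131 that rose and 780 that fell. The libraries of the groups did not overlap for 8773 of the changed genes and for 65.1% of all tested genes, where chance gives 10%. Scaling by library size alone moved the median of all genes from -0.029 to -0.18 (log2) and gave 3048 genes up and 5966 down, so that the balance of directions depends on the scaling. At a minimum of 5 CPM, 1474 genes passed 2-fold, 399 up and 1075 down.

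**Figure D1:**
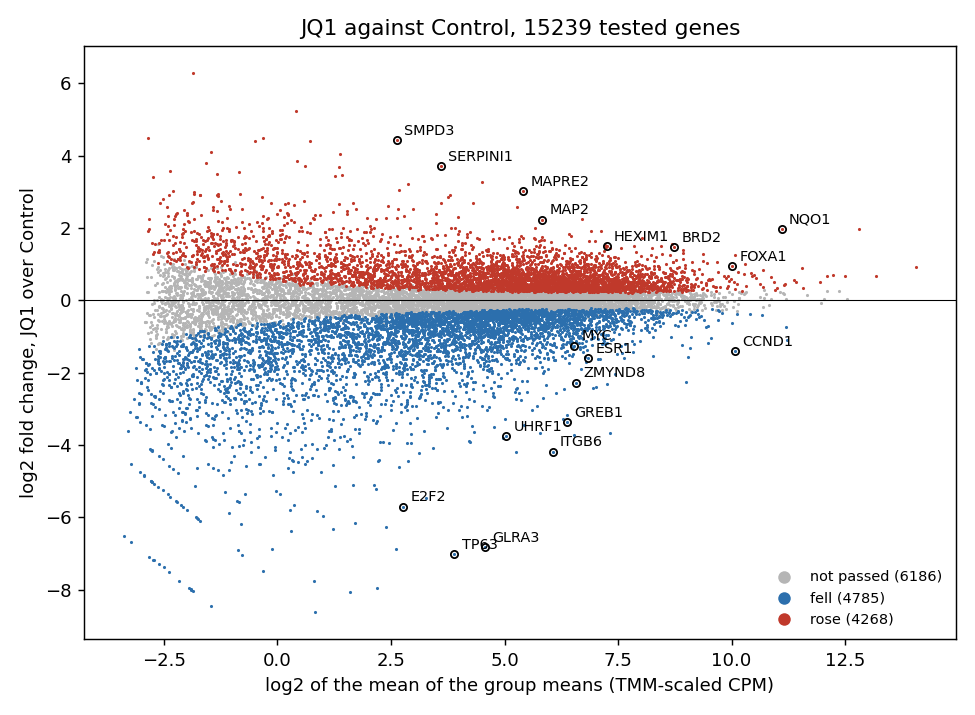
Log2 fold change (JQ1 over Control) of each tested gene against the log2 mean TMM-scaled CPM of the group means, with 3 libraries per group. Red points are the 4268 genes that rose, blue the 4785 that fell and grey the 6186 that did not pass an adjusted p of 0.05. Open circles mark 18 of the named genes, among them TP63 at -7.02 and SMPD3 at 4.43.

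The highest fold change among the genes named by rule was that of SMPD3, a neutral sphingomyelinase (chromosome 16, 68358327 to 68448508), which rose from 0.55 ± 0.22 to 11.8 ± 1.7 CPM (21.5-fold, adjusted p = 5.99e-09). SERPINI1, which encodes neuroserpin (chromosome 3, 167735721 to 167825569), rose from 1.71 ± 0.22 to 22.4 ± 1.06 CPM (13-fold, adjusted p = 4.43e-10). Genes of the cytoskeleton were among the 12: the microtubule-associated MAP1A rose 9.32-fold and MAPRE2 8.12-fold, the latter from 9.35 ± 0.49 to 75.9 ± 3.48 CPM. PAG1, a membrane adaptor of Src-family kinases, rose 9.71-fold, AHNAK2 7.54-fold, the RNA-binding NANOS1 6.49-fold, TEX14 6.44-fold and the adhesion adaptor SORBS1 6.11-fold. The other members were HIST2H2BC (6.01-fold), annotated as a transcribed histone pseudogene, and the U1 small nuclear RNA variants RNVU1-14 (7.21-fold) and RNVU1-15 (5.81-fold). Read assignment among near-identical copies is uncertain for these 3.

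The lowest fold change among genes of at least 5 CPM named by rule was that of TP63, a transcription factor of basal epithelial cells (chromosome 3, 189596746 to 189897276), which fell from 29.6 ± 6.73 to 0.23 ± 0.11 CPM (129-fold lower, adjusted p = 4.53e-10). The hyaluronidase gene SPAM1 was 116-fold lower, the glycine receptor subunit gene GLRA3 113-fold lower (47.4 ± 8.65 to 0.42 ± 0.091 CPM) and the deiodinase gene DIO2 77.5-fold lower. These 4 genes rested on 15 to 61 counts over the JQ1 libraries. E2F2 was 52.2-fold lower, BANK1 44.2-fold, BRINP2 24.3-fold and WDR76 21.7-fold. The hair keratin gene KRT86 was 18.6-fold lower and MALL 16.8-fold. ITGB6, an integrin subunit, and CCDC83 had higher levels in Control. ITGB6 (chromosome 2, 160099671 to 160200272) fell from 127 ± 26.4 to 6.97 ± 0.89 CPM (18.2-fold) and CCDC83 from 72.4 ± 10.5 to 3.99 ± 0.49 CPM (18.1-fold).

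Among regulators of the G1/S transition, 21 of 31 tested genes fell, 3 rose and 7 did not pass. CCND1, the cyclin D1 gene (chromosome 11, 69641156 to 69654474), fell from 1569 ± 135 to 597 ± 14.6 CPM, and its partner kinase genes CDK4 (-1.06 ± 0.10) and CDK6 (-1.03 ± 0.12) fell as well. CDK2 fell from 81.1 ± 0.37 to 33.8 ± 0.56 CPM, its cyclin genes CCNE1 and CCNE2 fell by 0.78 and 1.06 on the log2 scale, and CDC25A, a phosphatase that activates CDK2, fell by 2.59. E2F1 (chromosome 20, 33675477 to 33686385) fell from 17.6 ± 2.27 to 4.60 ± 0.49 CPM. RB1, the retinoblastoma gene, had 114 ± 13 CPM in Control and 123 ± 13.9 in JQ1 (adjusted p = 0.415), and the CDK inhibitor gene CDKN1A had 148 ± 13.8 and 154 ± 18.6 CPM (adjusted p = 0.690). The sign of both small differences depended on the scaling. With GC and length offsets the CDKN1A difference was 0.26 (log2) and passed, at an adjusted p of 0.00128. The genes that rose were CDKN2D (1.11), FBXW7 (0.29) and CDK7 (0.27), but this count ranged from 1 (without Control library 1, without JQ1 library 2 or with library size alone) through 5 (both libraries numbered 3 left out) to 7 (GC and length offsets). The list was lower than other genes by camera (adjusted p = 0.000577, and adjusted p = 0.0715 with an estimated correlation).

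Of 60 tested DNA replication and E2F target genes, 59 fell and none rose, with a median log2 fold change of -1.57. SLBP, at -0.17, was the only member that did not pass. UHRF1, which recruits maintenance DNA methylation (chromosome 19, 4903080 to 4962154), fell from 61.4 ± 4.68 to 4.57 ± 0.75 CPM. The replication licensing factor gene CDT1 fell from 50.01 ± 7.85 to 4.37 ± 0.86 CPM and DTL from 35.8 ± 5.29 to 3.25 ± 0.40 CPM. Camera gave an adjusted p of 1.27e-19, and an adjusted p of 0.0715 with an estimated correlation. Of 60 mitosis and G2/M genes, 57 fell, with a median of -1.24. HJURP, a centromere histone chaperone, fell by 2.37 on the log2 scale, CDCA5 by 2.37, the kinetochore gene SPC25 by 2.16 and the ubiquitin-conjugating enzyme gene UBE2C by 2.02. The proliferation marker MKI67 fell from 268 ± 35.4 to 112 ± 4.23 CPM. CDC25B rose (0.88), and CKAP2 (-0.20) and PTTG1 (-0.035) did not pass. The adjusted p was 4.60e-16, and with an estimated correlation the adjusted p was 0.0767.

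Replication-dependent histone genes, whose mRNAs accumulate in S phase, fell in 38 of 51 cases, with a median of -1.496. HIST1H4A (-3.23), HIST1H3F (-3.21), HIST1H2AB (-3.05) and HIST1H2BI (-3.02) had the largest changes, HIST1H3F from 20.4 ± 5.45 to 2.20 ± 0.084 CPM. The 4 that rose were HIST1H4I (2.52), HIST1H2AI (1.72), HIST1H3H (1.40) and HIST2H2BE (1.10), and 7 rose without Control library 3. Camera gave an adjusted p of 2.81e-07, and an adjusted p of 0.566 with an estimated correlation, which was high for this list (0.759).

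MYC (chromosome 8, 127735434 to 127742951) fell from 131 ± 6.58 to 55.1 ± 3.25 CPM, with an adjusted p of 1.42e-07. Of 45 tested MYC and ribosome biogenesis genes 37 fell and none rose. Besides MYC and CDK4, the members with the largest changes were TCOF1, a factor of ribosomal RNA transcription (-1.55 ± 0.12), and MRTO4, a ribosome assembly factor (-0.97 ± 0.12). The median was -0.53, smaller than for the cell-cycle lists, and 3 members passed 2-fold. The adjusted p was 7.38e-07, and with an estimated correlation the adjusted p was 0.0715. Of 76 ribosomal protein genes 18 fell, none rose and 58 did not pass, led by RPL30 (-0.68), RPL27A (-0.57), RPL11 (-0.47) and RPL21 (-0.45). Adjusted over the list alone, 4 fell. The count also depended on single libraries, with 34 falling without Control library 2 and 7 without Control library 1, Control library 3 or JQ1 library 2, and it was 41 with library size alone. As a list they did not pass (adjusted p = 0.0996), but passed without Control library 2 (adjusted p = 0.00479), with library size alone (0.0466) and at 5 CPM (0.0286). With both libraries numbered 3 left out, 16 fell and 12 rose. The call of RPL11 was also lost there (-0.15) and without Control library 3 (-0.27), JQ1 library 2 (-0.43) or JQ1 library 3 (-0.35).

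The estrogen receptor gene ESR1 (chromosome 6, 151656672 to 152129619) fell from 174 ± 15.4 to 57.2 ± 0.98 CPM, and the progesterone receptor gene PGR from 8.22 ± 1.95 to 2.87 ± 0.57 CPM. Of 37 estrogen-induced genes 26 fell and 8 did not pass. GREB1, an estrogen receptor cofactor (chromosome 2, 11482888 to 11642788), fell from 151 ± 7.75 to 14.6 ± 0.73 CPM, EGR3 from 10.8 ± 0.88 to 0.91 ± 0.13 CPM and the EGFR ligand gene AREG from 46.3 ± 13.7 to 7.80 ± 0.61 CPM. AGR3 had 154 counts over the Control libraries and none over the JQ1 libraries, which makes it at least 35.6-fold lower. TFF1 fell less (-0.49 ± 0.13). The 3 that rose were TIPARP (1.41), RET (0.35) and ADCY9 (0.30), and the call of RET was lost on scaling by library size alone (0.20). Camera gave an adjusted p of 3.13e-06, and an adjusted p of 0.0715 with an estimated correlation.

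Luminal identity genes went both ways, with 10 of 20 up and 5 down. FOXA1, a pioneer factor of luminal cells, rose from 708 ± 92.3 to 1361 ± 30.1 CPM, and TFAP2C (0.94) and GATA3 (0.36) rose, the last not passing on scaling by library size alone (0.21). MUC1 fell from 68.2 ± 1.55 to 11.6 ± 1.57 CPM, and ESR1, also a member of this list, fell by 1.60 on the log2 scale. No member rose by over 2-fold, and 2 fell by over 2-fold. The list did not pass (adjusted p = 0.171), but passed with GC and length offsets (adjusted p = 0.0137). Of 14 basal and myoepithelial markers 9 fell, led by TP63, CAV2 (-1.94) and CAV1 (-1.90), and 2 rose, KRT15 (1.52) and the laminin receptor subunit gene ITGA6 (1.24). Their adjusted p was 0.0246, and the adjusted p was 0.476 with an estimated correlation. The call was lost with both libraries numbered 3 left out (adjusted p = 0.0606) and with GC and length offsets (adjusted p = 0.153), although 9 fell and 2 rose in both settings and the medians were -1.04 and -1.01, against -0.985 with all libraries and no offsets.

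**Figure D2:**
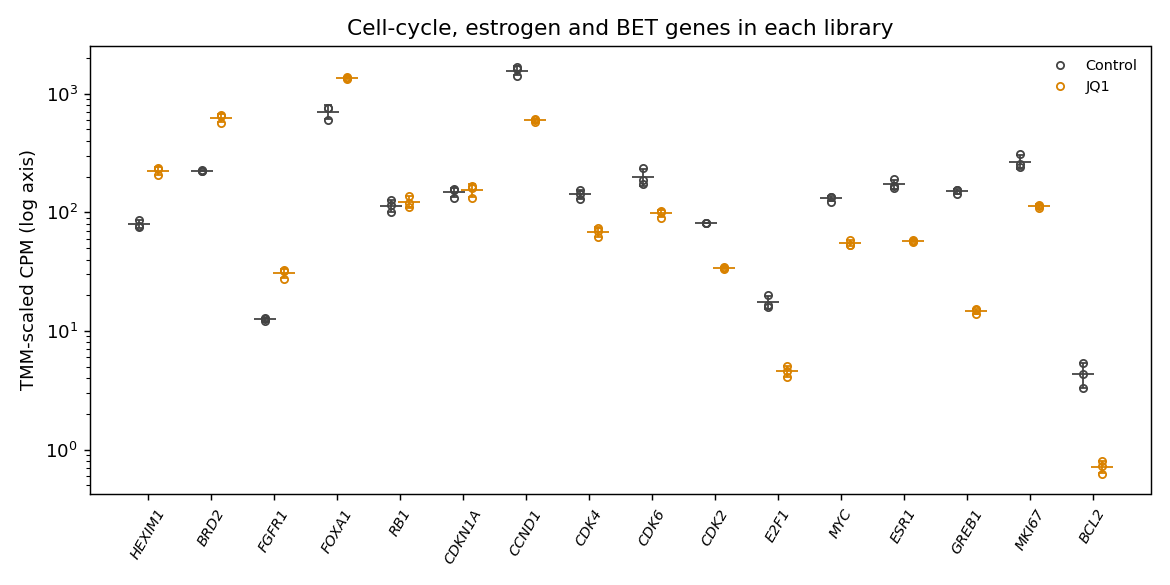
TMM-scaled CPM on a log axis for 16 genes fixed before the data were examined, with Control libraries in grey and JQ1 libraries in orange. Circles are single libraries, and dashes with bars are the mean ± SD of 3 libraries. HEXIM1, BRD2, FGFR1 and FOXA1 are higher with JQ1, RB1 and CDKN1A overlap between the groups, and the other 10 are lower with JQ1.

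Genes of BET proteins and of P-TEFb, the kinase that releases paused RNA polymerase II, rose in 14 of 27 cases and fell in 6. HEXIM1, the P-TEFb inhibitor gene (chromosome 17, 45148475 to 45152099), rose from 79.6 ± 6.38 to 225 ± 16.6 CPM (adjusted p = 5.82e-08), and its paralog HEXIM2 fell by 1.23 on the log2 scale. BRD2 (chromosome 6, 32968594 to 32981505) rose from 225 ± 2.61 to 625 ± 50.8 CPM, POLR2A, the largest subunit gene of RNA polymerase II, from 302 ± 13.2 to 667 ± 114 CPM, and BRD3 rose by a smaller amount (0.54 ± 0.093). BRD4 had 161 ± 9.57 and 181 ± 26.7 CPM (adjusted p = 0.216). It passed without JQ1 library 3 (0.28, adjusted p = 0.0139), without both libraries numbered 3 (0.24, adjusted p = 0.00623) and with GC and length offsets (0.28, adjusted p = 0.00656). CDK9, the kinase of P-TEFb, rose slightly (0.29 ± 0.096), a call that was lost without Control library 2 (0.25) or JQ1 library 2 (0.29) and on scaling by library size alone (0.15). The list passed (adjusted p = 0.0259, and adjusted p = 0.476 with an estimated correlation), except without JQ1 library 1 (adjusted p = 0.0725). Of the other fixed genes of the BET inhibitor response, ZCCHC24 rose from 9.83 ± 0.49 to 28.5 ± 1.23 CPM and ZMYND8 fell from 157 ± 6.22 to 32.6 ± 2.34 CPM.

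Growth factor receptors and adaptors showed no common direction, with 10 of 29 up and 11 down. Without JQ1 library 2, 6 fell, and with library size alone 6 rose. The median (0.013), mean (-0.023) and test (up) differed in sign, with an adjusted p of 0.685. FGFR1 (chromosome 8, 38411143 to 38468635) rose from 12.5 ± 0.38 to 30.6 ± 2.74 CPM and the insulin receptor substrate gene IRS2 from 4.05 ± 0.27 to 10.9 ± 1.23 CPM. MET fell from 44.9 ± 4.45 to 9.44 ± 0.38 CPM, and EGFR fell by 0.82 on the log2 scale. KIT fell (-1.63 ± 0.56) on 41 and 9 counts over the groups, and this call was lost without Control library 3 (-1.53), JQ1 library 2 (-1.42) or JQ1 library 3 (-1.30), without both libraries numbered 3 (-1.19) and with DESeq2 (-1.67, adjusted p = 0.0628). ERBB2 rose marginally (0.35 ± 0.13, adjusted p = 0.0280), with overlapping groups, and did not pass without Control library 1 (0.36) or 2 (0.29), without JQ1 library 1 (0.26) or 2 (0.32), on scaling by library size alone (0.20) or upper-quartile factors (0.31), or at 5 CPM (0.32).

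Of 29 AP-1 and MAPK-output genes 13 fell and 7 rose (adjusted p = 0.365). FOSL1, an AP-1 subunit gene, fell from 2.79 ± 0.88 to 0.13 ± 0.059 CPM and ETV4 from 1.70 ± 0.62 to 0.26 ± 0.048 CPM, while JUN rose from 37.3 ± 4.34 to 134 ± 9.44 CPM. NF-kB and inflammatory genes fell in 9 of 17 cases and rose in 4 (adjusted p = 0.162), but 2 rose without Control library 1, 2 or 3 or JQ1 library 3, and 1 with library size alone. LIF fell by 5.35 on the log2 scale, on 7 counts over the JQ1 libraries, CSF1 by 2.76 and RELB by 1.56, while CXCL8 rose by 2.71 from 15 counts over the Control libraries. Of 37 interferon-stimulated genes 18 fell and 7 rose. OAS2 was at 91 and 3 counts over the groups, SAMD9 fell by 3.82 on the log2 scale, HERC6 by 2.77 and PARP14 by 2.57. This list passed narrowly (adjusted p = 0.0450, and adjusted p = 0.232 with an estimated correlation), and did not pass with upper-quartile factors (adjusted p = 0.0532), library size alone (0.0713), at least 5 CPM (0.171) or GC and length offsets (0.0904). Its median was -0.405, and -0.448, -0.554, -0.331 (21 genes tested) and -0.382 in these settings. Epithelial-mesenchymal and TGF-beta genes fell in 13 of 32 cases and rose in 9 (adjusted p = 0.365), with SERPINE1 (-4.59), ITGB6, TGFB2 (-2.42) and COL3A1 (-1.41) changing most.

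Among 28 apoptosis regulators 10 rose and 13 fell (adjusted p = 0.535), and 6 rose without Control library 3 or with library size alone. The antiapoptotic BCL2 (chromosome 18, 63123346 to 63320090) fell from 4.35 ± 1.04 to 0.72 ± 0.086 CPM, the death receptor gene FAS from 7.16 ± 0.77 to 1.65 ± 0.13 CPM, CFLAR from 43.5 ± 3.13 to 16.1 ± 1.19 CPM and BIRC5 from 32.2 ± 2.91 to 12.3 ± 0.67 CPM. BCL2L11, which encodes the proapoptotic BIM, rose by a small amount (0.35 ± 0.11), a call lost without Control library 3 (0.25) and on scaling by library size alone (0.20). Of 31 p53 targets 12 rose and 7 fell (adjusted p = 0.351), and 9 rose and 9 fell with library size alone. Their median was 0.055, and it was -0.093 with library size alone, -0.029 without both libraries numbered 3 and -0.0023 without JQ1 library 3. TP53I3 (1.78) and GADD45A (1.39) rose, and FAS and SPATA18 (-1.43) fell.

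Lysosome and autophagy genes rose in 25 of 43 cases and fell in 4, with a median of 0.35 and an adjusted p of 0.00183 (adjusted p = 0.476 with an estimated correlation). MAP1LC3B, which encodes an autophagosome membrane protein, rose from 271 ± 25.4 to 711 ± 57.9 CPM and the lysosomal channel gene MCOLN1 from 8.76 ± 1.12 to 17.4 ± 4.09 CPM. TFEB, a transcription factor of lysosomal genes, fell from 1.85 ± 0.41 to 0.45 ± 0.051 CPM, and ATG9B (-1.51), CTSH (-0.40) and CTSD (-0.37) also fell. NRF2 and iron or redox genes rose in 15 of 27 cases and fell in 6. NQO1, a quinone reductase, rose from 890 ± 65.6 to 3514 ± 33.7 CPM, while GPX2 (-2.39), AKR1C2 (-2.35) and AKR1B10 (-1.78) fell. This list missed the threshold (adjusted p = 0.0587), but passed without JQ1 library 3 (adjusted p = 0.0356), with library size alone (0.0466), without a filter (0.0304), at 5 CPM (0.00668) and with GC and length offsets (0.0219).

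Of 27 genes of the unfolded protein response 13 rose and 8 fell, but 8 rose without Control library 1 or JQ1 library 2, 7 at 5 CPM and 6 with library size alone, where 8 fell. Their median (0.18), mean (-0.021) and test (up) differed in sign, with an adjusted p of 0.454, and CHAC1 (-1.32), TRIB3 (-1.09), PHGDH (-0.99) and SDF2L1 (-0.90) changed most. Cholesterol synthesis genes rose in 6 and fell in 9 of 23 cases (adjusted p = 0.669), and 5 fell without Control library 3. FDPS fell from 115 ± 36.4 to 49.98 ± 4.17 CPM and MVK by 0.87 on the log2 scale, while IDI1 (0.85) and LSS (0.76) rose. Of 15 neuronal genes 7 rose and 3 fell (adjusted p = 0.162). Besides SERPINI1, MAP2 rose from 19.9 ± 1.41 to 93.4 ± 2.95 CPM and SYP by 2.15 on the log2 scale, and SYT1 fell from 105 ± 11.1 to 33.5 ± 1.55 CPM.

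Of 8 tested fibroblast and endothelial markers 5 fell. These were CDH5, ERG and LUM, at 0.27 to 3.79 CPM in Control, and the collagen genes COL1A1 (15.7 CPM) and COL3A1 (120 ± 4.93 CPM). KDR rose from 0.72 ± 0.17 to 3.97 ± 0.42 CPM. The list missed the threshold (adjusted p = 0.0568), but passed without Control library 1 (adjusted p = 0.0463), JQ1 library 2 (0.0259) or JQ1 library 3 (0.0474) and with DESeq2's size factors (0.0492). Of the leukocyte markers 3 could be tested, too few for the set test. CD8A fell (-0.85), and LYZ (0.69) and CD68 (0.080) did not pass, while 1 marker rose without Control library 1. Their median (0.080) and mean (-0.027) differed in sign.

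**Figure D3:**
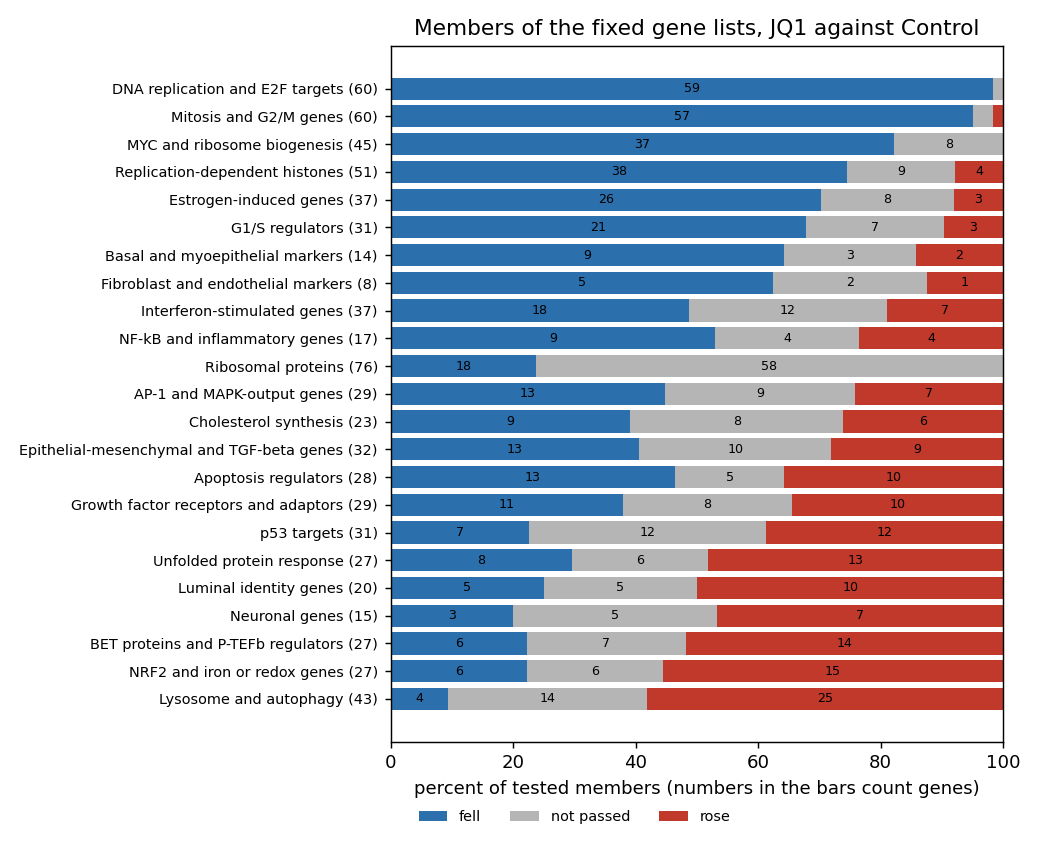
Share of the tested members of each fixed gene list that fell (blue), did not pass (grey) or rose (red) with JQ1, as percent of tested members, with the number of genes in the bars and the number tested in parentheses. DNA replication and E2F targets (59 of 60) and mitosis genes (57 of 60) hold the highest shares that fell, and lysosome and autophagy genes (25 of 43) the highest share that rose.

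In all, 10 of the 23 tested lists passed with the preset correlation of 0.01, and none passed with a correlation estimated per list (lowest adjusted p = 0.0715). For the estrogen, G1/S and interferon lists the estimated correlation was below the preset value (-0.0173, -0.0109 and 0.00289). The loss of these calls is therefore not a result of more strongly correlated genes. For the estrogen list the unadjusted camera p rose from 6.8e-07 to 0.0044 although the correlation was lower. The estimated setting thus differs from the preset one in more than the correlation. Its p-values alone do not show that a list's genes vary together. Of the 32 fixed genes 12 rose, 17 fell and 3 did not pass, and the counts adjusted over the list alone were the same.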

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

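Thinning, GC and length offsets and leaving out both libraries numbered 3 were chosen after the data were seen. The count of changed genes, 9053, lay between 6493 (at least 5 CPM) and 9943 (both libraries numbered 3 left out, of which 8364 were shared) under all 19 alternatives, and no gene changed direction between calls. No label says whether equal library numbers belong together. Their deviations from the group means were not positively correlated (-0.000283, -0.117 and -0.324), which cannot exclude pairing with so few libraries. The replicate block gave 7813 genes, without CDK9 (adjusted p 0.0626), BCL2L11 (0.0539) and ERBB2 (0.071). Genes over 2-fold moved by more than 1.5 times at 1 setting, at least 5 CPM (1474, with 399 up and 1075 down), which tests fewer genes. The lists depended most on the set test. With an estimated correlation 0 passed: adjusted p 0.0715 for E2F, G1/S, MYC and estrogen genes, 0.0767 for mitosis, 0.232 for interferon genes, 0.476 for BET, lysosome and basal genes and 0.566 for histones. With fry, which does not compare a list with other genes, 18 passed, adding NF-kB (0.0123), AP-1 (0.0202), apoptosis (6.82e-05), p53 (0.00101), epithelial-mesenchymal (0.00589), NRF2 (0.00969), neuronal (6.82e-05) and fibroblast and endothelial genes (0.000191). Fibroblast and endothelial markers also passed with DESeq2's size factors (0.0492). NRF2 genes passed with library size alone (0.0466), no filter (0.0304), 5 CPM (0.00668) and GC offsets (0.0219), and ribosomal proteins with library size alone (0.0466) and 5 CPM (0.0286). Interferon genes did not pass with library size alone (0.0713), upper-quartile factors (0.0532), 5 CPM (0.171) or GC offsets (0.0904). GC offsets also gave 0.0137 for luminal and 0.153 for basal genes, and 0.998 with the opposite direction for receptors, cholesterol genes and ribosomal proteins. Basal genes were at 0.0606 without both libraries numbered 3. Leaving out 1 library gave 0.0259 to 0.101 for fibroblast and endothelial markers, 0.00479 to 0.469 for ribosomal proteins, 0.016 to 0.0725 for BET genes, 0.0356 to 0.103 for NRF2 genes and a log2 fold change of -0.0238 to 0.147 for CDKN1A. RB1 changed sign with library size alone (-0.0371), GC offsets (-0.0890) and without both libraries numbered 3 (-0.0636), and CDKN1A with library size alone (-0.0932). Apart from what their construction shows, the cause of these changes was not tested. Depth limits the folds of genes that JQ1 left with few counts.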

Other observations

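The comparison of gene families and the tests below were chosen after the results were seen, except those of GC bias, whose outcome was stated before. Of 190 families of genes that share the letters of their symbol, zinc finger genes (ZNF) rose more often than other genes: 188 of 462 rose (40.7%, against 28.0% of all tested genes, adjusted p = 3.74e-07 by Fisher's exact test) and 101 fell. Among ZNF genes with at least 5 CPM, ZNF10 rose from 3.61 ± 0.31 to 18.7 ± 1.15 CPM, and ZNF618 fell from 34.9 ± 2.50 to 2.37 ± 0.13 CPM. Other genes of the same GC content rose in 30.6% of cases. Of 50 mitochondrial ribosomal protein genes named MRPL none rose and 23 fell. By Fisher's exact test the adjusted p was 6.06e-06 for the share that rose, but 0.26 for the share that fell. MRPL3 fell from 214 ± 23.7 to 94.3 ± 4.86 CPM. Of 30 mitochondrial ribosomal protein genes named MRPS 5 rose and 11 fell (adjusted p = 0.638 and 0.856 by Fisher's exact test). Genes sharing the letters RPL also rose rarely: 2 of 61 rose and 20 fell (adjusted p = 4.54e-05 and 0.983 by Fisher's exact test). A lack of genes that rose was thus not particular to MRPL genes. Further families that passed are not listed here. Of 75 genes named ATP, mostly ion pumps and ATPase subunits, 40 rose (53.3%, adjusted p = 0.000146 by Fisher's exact test), among them the sodium pump subunit gene ATP1B3 (79.7 ± 4.73 to 220 ± 20.6 CPM). With library size alone 133 ZNF genes rose and 137 fell, against 20% and 39.1% of all genes, and 21 ATP genes rose (28%). Without both libraries numbered 3, 193 ZNF and 46 ATP genes rose, and 6 MRPL genes rose while 26 fell. Genes are not independent, so these p-values are only a guide.

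Some single genes outside the fixed lists are named here after their values were seen, with no test of them as a group. The long noncoding RNA NEAT1, the scaffold of paraspeckles, rose from 2896 ± 549 to 11355 ± 1288 CPM, and MALAT1 from 11833 ± 1051 to 22335 ± 2548 CPM. MALAT1 alone took 1.19% to 1.35% of the counts in Control and 1.94% to 2.35% in JQ1. The replication-independent histone gene H3F3B rose from 932 ± 23.2 to 1557 ± 26.2 CPM and the linker histone gene H1F0 from 271 ± 9.39 to 384 ± 52.1 CPM. The macroH2A gene H2AFY2 fell from 13.6 ± 0.97 to 0.87 ± 0.10 CPM.

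More genes fell than rose by over 2-fold: 29.8% of the 3158 genes rose. The tables argue against the choice among 4 scalings as the whole cause, since that share was at most 31.4% and at least 20.6% over them. With TMM scaling kept, that share was 29.9% after thinning and 28.5% with GC and length offsets. For this scaling only, these values argue against unequal depth and against a trend with GC content or transcript length. A shift of all genes by 0.268 on the log2 scale would equalise the directions. The 4 scalings kept the median of all genes between -0.178 and -0.00891, so they did not test a scaling error of this size. Thinning and the offsets did not test it either, with medians of -0.0278 and -0.0413. Both kept the TMM scaling, and the offsets were centred within each library. Without spike-in RNA, a change in total RNA per cell stays open, as does an effect of JQ1 on transcription, which may lower more genes than it raises but was not tested apart from it.

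GC-rich transcripts were lower in JQ1. The median log2 fold change went from 0.157 in the most GC-poor decile, where 38.3% of genes rose and 21.7% fell, to -0.311 in the most GC-rich decile, where 14.2% rose and 42.9% fell. A GC bias of single libraries may account for it: the gap between the groups in the GC contrast, -0.478, was smaller than the widest range within a group, 0.769, and was -0.0951 without both libraries numbered 3. A GC bias shared by a group's libraries cannot be told apart from JQ1 itself, since the GC contrast of the fold changes differed by 0.261 ± 0.124 (bootstrap SD) between the highest and lowest of 3 expression classes, too close to the bound of 0.2 set before. JQ1 acting on GC-rich genes stays open and was not tested.

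Of 17 genes of small nuclear RNAs of the spliceosome and related classes 15 rose and none fell, with a median of 1.73, from low levels (median 0.925 CPM in Control). Better recovery of all short RNAs is argued against, since 10 small Cajal body RNA genes of 200 bp or less had a median of 0.0126 ± 0.225 (bootstrap SD). These genes were low too, with a median of 0.489 CPM in Control. Among other short RNAs SNORD3D rose (1.91, adjusted p = 4.23e-05) and SNORD3A did not pass (0.43). Better recovery of some short RNAs only therefore stays open. The 10 genes other than U1 copies had a median of 1.31, and for the U1 copies movement of reads between near-identical copies cannot be told apart from a rise: 0 of the 8 tested copies fell, including RNVU1-11, annotated as a pseudogene and not among the 17, but the main U1 genes are listed at 0. RN7SK, which holds P-TEFb inactive, had 5840 ± 773 CPM in Control and 6030 ± 1330 in JQ1. Reads from longer unprocessed transcripts running through these genes, which could raise their counts, and an effect of JQ1 on their synthesis were not tested.

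The counts were also made for other splits of the 6 libraries. The real split gave 9053 changed genes, 3158 over 2-fold and 29 of the fixed genes. It was in each case the only 1 of the 10 splits to reach its value, the highest other value being 0. The other splits mix Control and JQ1 libraries in each group, so the JQ1 difference becomes spread within the groups. A count of 0 there was largely set by this design and says little about chance. For the 10 lists that passed, 3 of the 10 splits gave as many, and the highest other value was 12. With 10 splits a share under 0.05 cannot be reached. The real split gave the lowest camera value of the 10 for the E2F, mitosis, G1/S, MYC, estrogen and histone lists, but a mixed split came close for histones (5.36e-08 against 3.66e-08, unadjusted) and MYC (3.01e-07 against 1.28e-07). For E2F and mitosis the lowest mixed splits gave 3.7e-13 and 5.7e-13. For the lysosome, basal and interferon lists 3 of the 10 splits gave a value as low, and for the BET list 4 did. Camera with the preset correlation thus also passes lists between mixed groups of these libraries. These groups hold unequal numbers of JQ1 libraries, so part of the JQ1 difference remains between them. The low values there are therefore no measure of how camera acts without a treatment difference.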
